A study of Homo sapiens with 4 samples.

How the data were processed

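Polyadenylated RNA of LNCaP cells was sequenced in 4 libraries: 2 of cells carrying the empty vector and 2 of cells overexpressing HOXD13. Cells were grown in RPMI-1640 with serum, infected with lentivirus and selected with puromycin, and mRNA was enriched with oligo(dT) from total RNA, per the labels' protocols. Reads were processed with Bowtie2 and RSEM, with the genome builds hg18 and hg19 named, per the submitters' processing notes; versions and the role of each build are not given in the sources used here. No genomic positions are reported for that reason.

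Each library has a table of RSEM expected counts, lengths and FPKM per RefSeq gene, per the file headers. Genes missing from a library's table were given 0 expected counts. A deposited table holds FPKM for all 4 libraries, per the file headers, and its values were the same as those of the library tables. Expected counts are estimates that divide a read shared by several genes among them, so they can be fractional; they were rounded to whole counts for the tests. Of the 2260 called genes, 767 share reads with other genes, and their values are uncertain by that share. FPKM are printed as deposited, with mean and SD over the 2 libraries of a group. CPM, log2 values, fold changes and all p-values were computed here. No deposited comparison was used.

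Total expected counts ranged from 6881110 to 8530487. Differences in counts between replicates were compared with sampling noise by chi-square over genes with at least 20 counts in the pair. The comparison was HOXD13 minus empty vector, fixed before the data were examined together with the tests, thresholds, alternatives, gene lists and the rule for naming genes. The test was the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) on rounded expected counts with TMM normalization and the filterByExpr filter, which kept 14112 genes. TMM factors were 0.995 to 1.01, and the biological coefficient of variation was 2.70%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is the one implied by the quasi-likelihood test. It is the absolute log2 fold change divided by the square root of the F statistic. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 and was not used. For HOXD13, with 0 counts in the empty-vector group, the fold is a bound against a floor of 3 counts over that group, the 95% Poisson limit.

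There were 32 gene lists with 638 members, written from textbook knowledge, covering HOX genes, BMP and TGF-beta signalling, epithelial, mesenchymal and matrix genes, androgen response, luminal, neuroendocrine and basal identity, cell cycle, stress, metabolic and signalling programmes, and markers of fibroblasts, leukocytes and endothelium. The 28 lists with at least 5 tested members were tested with limma camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists. Lists are partly overlapping. Some individual list members are not reported here. The named genes are HOXD13, SMAD1 and BMP4, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM and non-overlapping groups, up to 4 called members of each list by size of change or, where no member was called, up to 2 with the smallest p, given as values, and called HOX genes. The rule aimed at about 45 genes, and the text names more because 32 lists were described; genes outside the rule are said to be chosen after their values were seen, and FASN and SORD are among them.

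Alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 Wald test (DESeq2 1.42.0), limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 2 libraries, no low-count filter, a mean of at least 50 counts, the replicate number as a block, each library left out in turn, and stricter thresholds (adjusted p under 0.01, or an absolute log2 fold change of at least 1). For lists they were camera with estimated correlation, fry, log2(FPKM + 1) values, the block and each library left out. Chosen after the data were seen were the removal of expression, length and GC trends per library with smooth terms (mgcv 1.9.3), the sums of near-identical copies, and camera on the authors' GO terms of 10 to 300 tested genes. GC fractions came from GENCODE transcripts for 95.8% of tested genes. Groups of 2 libraries do not permit an outlier rule, and no library was left out of the reported results.

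The tests were tested on simulated data of the same size, with 50 changed genes per fold. These were far fewer changed genes among the 14112 simulated than the 2260 called in the data. Recovery at an adjusted p depends on the share of changed genes, so the percentages describe the simulation only. They do not give the share of true changes found in these libraries. The edgeR test recovered 30.0% of 1.2-fold, 62.0% of 1.5-fold, 76.0% of 2-fold and 94.0% of 4-fold changes, and called 16 unchanged genes. DESeq2 recovered 8.00%, 46.0%, 66.0% and 86.0% and called 4 unchanged genes, and limma recovered 8.00%, 40.0%, 60.0% and 80.0% and called 4. In the simulation, unchanged genes took a larger share of the edgeR calls than the adjusted p threshold of 0.05 allows. For DESeq2 and limma that share stayed below 0.05. The edgeR calls in the data may likewise hold more false calls than that threshold allows. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.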

Results

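RNA-seq measured polyadenylated RNA from LNCaP, an established androgen-responsive human prostate cancer cell line, after lentiviral infection and puromycin selection. There were 2 groups of 2 libraries: cells carrying the empty vector and cells overexpressing HOXD13, a homeobox transcription factor of the HOXD cluster. Total expected counts were 7662978 and 6881110 for empty-vector replicates 1 and 2, and 8530487 and 8335067 for HOXD13 replicates 1 and 2. The deepest library held 1.24 times the total of the shallowest, and the 10 most abundant genes took 3.44% to 3.49% of the counts in each library. Counts of the replicates differed by more than sampling noise, with a chi-square to degrees of freedom ratio of 1.57 for the empty-vector pair and 1.75 for the HOXD13 pair, against 5.24 to 5.95 between groups. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

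The comparison asked which transcripts differ when HOXD13 is overexpressed, and the series title places SMAD1, BMP4 and the epithelial-mesenchymal transition at the centre of that question. HOXD13 (gene ID 3239) itself had 0 counts in both empty-vector libraries and 88 and 104 counts in the HOXD13 libraries. Its level in the HOXD13 libraries was 4.87 ± 0.651 FPKM (SD, n = 2). The HOXD13 group reached 11.3 CPM, and a floor of 3 counts over the empty-vector group equals 0.208 CPM. HOXD13 was therefore at least 54.6-fold higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.12e-12). That floor covers counting error only. The labels of all 4 libraries therefore matched the level of the overexpressed gene. Of the 16 HOX genes with enough counts to be tested, HOXB13, a prostate lineage factor, was the other one that passed the threshold, at 136 ± 3.21 FPKM with the empty vector and 128 ± 0.636 FPKM with HOXD13 (log2 fold change -0.11, SE 0.0357, adjusted p = 0.0353). The HOXB13 call was lost without empty-vector replicate 1 (adjusted p = 0.311), without empty-vector replicate 2 (0.0701) and with expression, length and GC trends removed (0.0896). It was also lost with the DESeq2 Wald test (adjusted p = 0.0804) and with limma on log2(FPKM + 1) (0.198). Below, losses of single-gene calls are listed mainly for left-out libraries and removed trends. The DESeq2 Wald test and limma ended further calls. The HOX list includes HOXD13 itself, so a test of the list cannot show that the other HOX genes rose. Of its 16 tested members, 14 were not called. The list was not called by camera (adjusted p = 0.560), but the fry test called it (0.0342). Its median log2 fold change of 0.02 was not stable: it was 0.17 and -0.08 without empty-vector replicates 1 and 2, and 0.07 and -0.04 without HOXD13 replicates 1 and 2.

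HOXD13 overexpression came with many changes of small size. Among 14112 genes tested, 1116 (7.91%) were higher and 1144 (8.11%) were lower in the HOXD13 libraries, with a median absolute log2 fold change of 0.25 among the 2260 called genes. Changes of at least 2-fold were rarer and mostly rises, with 75 genes higher and 18 lower. Fold changes also ran higher at low expression. The median log2 fold change was 0.14 in the lowest of 10 bins of expression and -0.06 in the highest. How far the excess of 2-fold rises reflects this trend was not tested. The strongest rises included genes for signalling and secreted proteins, and the strongest falls included a G protein subunit, a potassium channel and a laminin chain. The groups did not overlap for 7630 genes (54.1%), where chance gives 33.3% for 2 libraries against 2. The calls came from the edgeR quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. The DESeq2 Wald test with its own filter, which left 11567 of 18673 genes without an adjusted p, called 473 genes higher and 577 lower. Limma on log2(FPKM + 1) over 13520 genes called 398 higher and 261 lower. Without empty-vector replicate 1 or 2, 714 or 759 genes were lower.

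Among the 10 largest rises at a mean of at least 5 FPKM, NDUFA4L2, a mitochondrial protein gene induced by hypoxia, went from 11.6 ± 0.0354 to 39.0 ± 6.70 FPKM (SD, n = 2 in each group; log2 fold change 1.73, SE 0.124, adjusted p = 1.45e-11). ADRA2A, the alpha-2A adrenergic receptor, rose from 6.32 ± 0.509 to 19.0 ± 0.523 FPKM (log2 fold change 1.58). CBLN2, a secreted synaptic organiser, rose from 18.2 ± 0.0849 to 42.5 ± 1.98 FPKM (log2 fold change 1.21). GDF15, a secreted member of the TGF-beta superfamily, rose from 204 ± 4.66 to 432 ± 8.52 FPKM (log2 fold change 1.06, SE 0.0375, adjusted p = 8.71e-20). The synaptic vesicle gene SYT4 (log2 fold change 1.06), the lactate exporter SLC16A3 (1.01) and the semaphorin and VEGF co-receptor NRP1 (0.92) also rose. The mannosidase MANEA (0.92), the secreted glycoprotein FSTL1 (0.86) and the prostatic acid phosphatase ACPP (0.85) completed this group. The 10 genes were chosen only from those with both HOXD13 libraries above both empty-vector libraries. The expected counts of ACPP were fractional, so some of its reads were shared with other genes and its value is uncertain by that share.

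GNAI1, a subunit of inhibitory G proteins, fell from 6.91 ± 0.417 to 3.18 ± 0.127 FPKM (SD, n = 2; log2 fold change -1.13, SE 0.144, adjusted p = 8.82e-07). The potassium channel gene KCNMA1 fell from 11.9 ± 0.0212 to 5.99 ± 0.247 FPKM (log2 fold change -1.12). DHRS2, a short-chain dehydrogenase, fell from 9.77 ± 0.842 to 4.91 ± 0.820 FPKM. LAMA3, a laminin chain of the epithelial basement membrane, fell from 10.8 ± 0.559 to 6.82 ± 0.141 FPKM (log2 fold change -0.72). ID3 (log2 fold change -0.76), C1orf74 (-0.74), CTH (-0.65) and HNRNPH2 (-0.65) were also among the 10 largest falls. The C1orf74 call was lost without empty-vector replicate 1 (adjusted p = 0.183) and without HOXD13 replicate 1 (0.0577), and the CTH call without empty-vector replicate 2 (0.274, log2 fold change -0.43). GAGE12F and GAGE2C, which belong to a family of near-identical cancer-testis antigen genes, had 187 and 132 counts over the empty-vector group and 0 over the HOXD13 group. Reads of GAGE copies cannot be assigned with certainty, so these zeros give no bound on a fold, and the summed counts of the 8 family members had a log2 fold change of -0.13 (SE 0.0425, adjusted p = 0.0341). KCNMA1, DHRS2, CTH and HNRNPH2 also had fractional counts and are uncertain by the share of reads they had in common with other genes.

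**Figure D1:**
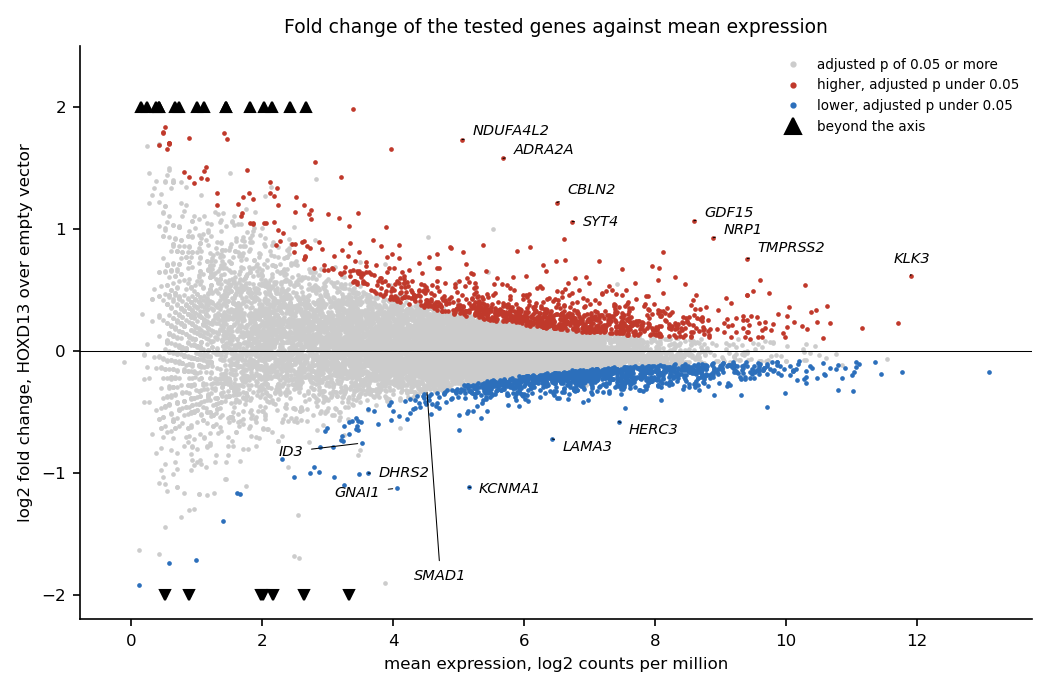
Log2 fold change of HOXD13 over empty-vector libraries (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 14112 tested genes, 1 point per gene. The 1116 red and 1144 blue points passed an adjusted p of 0.05, grey points did not, and black triangles mark genes whose fitted value lies beyond the axis, HOXD13 among them.

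The called changes among BMP-SMAD target genes were falls, and the difference in SMAD1 itself did not pass the threshold. SMAD1 (gene ID 4086), a transducer of BMP signals, was at 8.23 ± 0.00707 FPKM with the empty vector and 6.65 ± 0.325 FPKM with HOXD13 (SD, n = 2), a log2 fold change of -0.31 (SE 0.121). This did not pass the threshold (edgeR adjusted p = 0.0795). Both HOXD13 libraries lay below both empty-vector libraries, but the groups did not overlap for 54.1% of all tested genes. With expression, length and GC trends removed from each library, a correction chosen after the data were seen, the log2 fold change was -0.36 and the adjusted p 0.0390, within a range of 0.0390 to 0.308 over the alternatives. Of 11 tested BMP-SMAD target genes, 3 were lower and 8 were not called (4 lower when adjusted over the list alone). The median log2 fold change was -0.47, against -0.28 without HOXD13 replicate 1 and -0.29 on log2(FPKM + 1). ID3 went from 11.6 ± 0.0919 to 6.91 ± 0.566 FPKM (log2 fold change -0.76, adjusted p = 0.00231), ID2 from 4.47 ± 0.205 to 2.43 ± 0.382 FPKM (-0.89, adjusted p = 0.0342) and the inhibitory SMAD gene SMAD6 from 4.36 ± 0.820 to 3.32 ± 0.488 FPKM (-0.58, adjusted p = 0.0493). ID1, named after its values were seen, had a log2 fold change of -0.53 and an adjusted p of 0.0888. The list was called lower (camera adjusted p = 0.00203), but not with a correlation estimated from the data (adjusted p = 0.271 with an estimated correlation). The ID2 call was lost without empty-vector replicate 1 (adjusted p = 0.107), empty-vector replicate 2 (0.160) or HOXD13 replicate 2 (0.173). The SMAD6 call was lost without empty-vector replicate 2 (0.473, log2 fold change -0.33) or HOXD13 replicate 1 (0.337, -0.38), and on log2(FPKM + 1) its value was -0.31.

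Among genes of the BMP pathway itself, the called changes were rises. Of 17 tested components, 3 rose and 14 were not called (4 higher when adjusted over the list alone). The ligand gene BMP6 (log2 fold change 0.44, adjusted p = 0.0481) and the receptor genes BMPR1B (0.33, adjusted p = 0.00230) and BMPR2 (0.27, adjusted p = 0.000147) rose. With limma on log2(FPKM + 1) the calls of BMP6 (adjusted p = 0.166), BMPR1B (0.085) and BMPR2 (0.0835) were lost. The list as a whole was not called (median log2 fold change 0.05, camera adjusted p = 0.289). The median was 0.10 without empty-vector replicate 1 or HOXD13 replicate 2, 0.02 without empty-vector replicate 2 and 0.03 with the trends removed. BMP4 had 3 and 0 counts with the empty vector and 0 and 4 counts with HOXD13, so that no difference was detectable at this depth. The BMP6 call was lost without empty-vector replicate 2 (adjusted p = 0.398, log2 fold change 0.26), without HOXD13 replicate 1 (0.244) and with the trends removed (log2 fold change 0.38). Without empty-vector replicate 1 the BMP6 log2 fold change was 0.67. The BMPR1B call was lost without empty-vector replicate 1 (0.0814). TGF-beta target genes were called higher as a list, with 2 of 11 members higher and 9 not called, the same 2 when adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 0.0333, adjusted p = 0.306 with an estimated correlation). PMEPA1, an inhibitor of TGF-beta and androgen signalling, rose from 42.8 ± 0.856 to 54.6 ± 1.29 FPKM (log2 fold change 0.33, adjusted p = 9.95e-07). PMEPA1 and BMPR1B also belong to the androgen-induced list and are counted among its rises. The matrix protein gene LTBP2 rose from 0.515 ± 0.0636 to 0.930 ± 0.0283 FPKM (log2 fold change 0.84, adjusted p = 0.0172). The TGF-beta call was lost without empty-vector replicate 1 (adjusted p = 0.0708), HOXD13 replicate 1 (0.0681) or HOXD13 replicate 2 (0.0930). With the trends removed it was lost as well (0.178), at a median of 0.06. The LTBP2 call was lost without empty-vector replicate 2 (0.123) or HOXD13 replicate 1 (0.0733) and with the trends removed (0.0780).

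**Figure D2:**
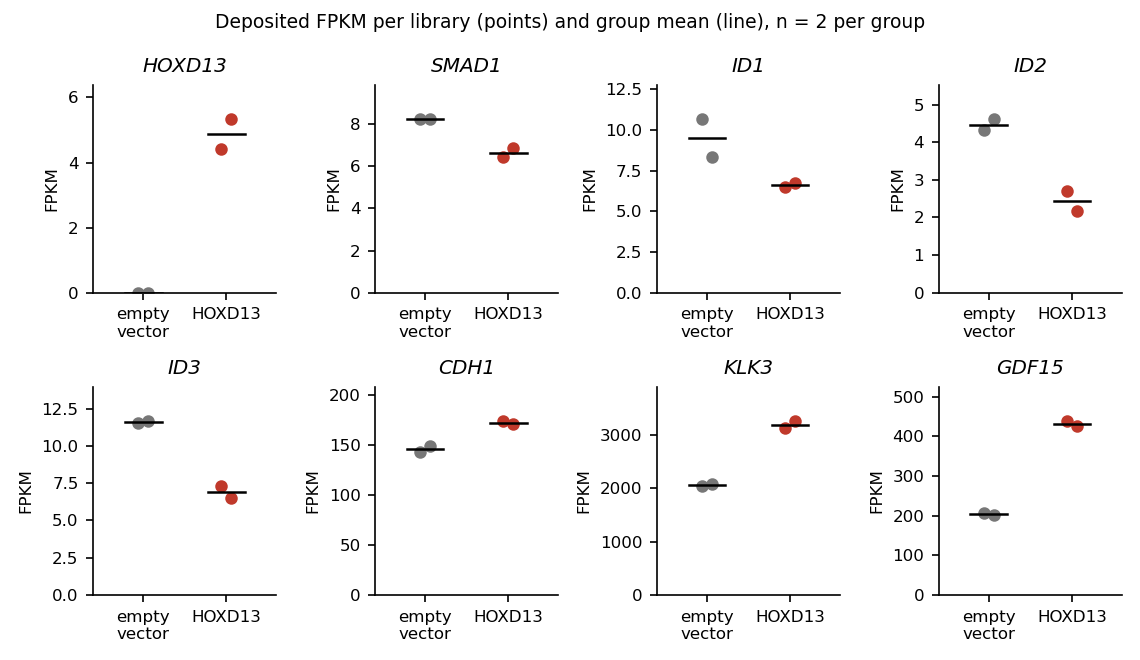
Deposited FPKM (vertical axes, starting at 0) of 8 genes in each library, with points for the 2 libraries of a group and a line at the group mean; grey is the empty vector and red is HOXD13. HOXD13 was at 0 in both empty-vector libraries, and for each of the other 7 genes both libraries of a group lay on the same side of both libraries of the other. Groups did not overlap for 54.1% of all tested genes.

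More epithelial junction genes rose than fell with HOXD13, and most were not called. Of 25 tested members, 10 rose, 1 fell and 14 were not called (12 higher and 1 lower when adjusted over the list alone). The tight junction gene OCLN rose from 20.3 ± 0.735 to 29.4 ± 1.99 FPKM (log2 fold change 0.53, adjusted p = 4.72e-09). CLDN4 rose from 108 ± 0.622 to 149 ± 1.53 FPKM (log2 fold change 0.45), CLDN3 from 54.1 ± 1.39 to 68.5 ± 2.19 FPKM (0.32) and the adhesion molecule EPCAM from 49.5 ± 1.06 to 62.6 ± 1.17 FPKM (0.32). CDH1, the gene of E-cadherin, rose to 172 ± 2.11 FPKM from a mean of 146 (log2 fold change 0.22, adjusted p = 3.40e-06). PKP3 fell (log2 fold change -0.23, adjusted p = 0.00120). Both were named after their values were seen. The list was called higher (median log2 fold change 0.16, camera adjusted p = 0.0299, adjusted p = 0.289 with an estimated correlation). With the replicate number as a block that call was lost (camera adjusted p = 0.0665). The list call was lost without empty-vector replicate 2 (adjusted p = 0.159), HOXD13 replicate 1 (0.0681) or HOXD13 replicate 2 (0.0711). The PKP3 call was lost without empty-vector replicate 1 (0.0699). OCLN, CLDN4, CLDN3 and CDH1 had fractional counts and are uncertain by the reads they shared with other genes.

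Few mesenchymal genes were called, and 11 of the 25 in the list had enough counts to be tested. Of these, 3 rose, 1 fell and 7 were not called (4 higher and 2 lower when adjusted over the list alone). The list was not called (median log2 fold change 0.21, camera adjusted p = 0.289), and its median was 0.34 without HOXD13 replicate 2 and 0.09 with the trends removed. LOX, which cross-links collagen, rose from 1.85 ± 0.417 to 3.34 ± 0.148 FPKM (log2 fold change 0.86, adjusted p = 0.000372). The transcription factor gene TWIST1 rose from 10.0 ± 0.707 to 13.7 ± 0.686 FPKM (0.44, adjusted p = 0.0181), and the fibronectin receptor gene ITGA5 also rose (0.34, adjusted p = 0.00960). FN1, the gene of fibronectin, fell from 30.2 ± 0.559 to 24.8 ± 0.523 FPKM (log2 fold change -0.29, adjusted p = 6.37e-06). VIM, named after its values were seen, was at 2.34 ± 0.0495 and 2.73 ± 0.615 FPKM (adjusted p = 0.677). The TWIST1 call was lost without empty-vector replicate 1 (adjusted p = 0.147) or HOXD13 replicate 1 (0.116), and the ITGA5 call without empty-vector replicate 1 (0.253, log2 fold change 0.21). The matrix protease and integrin list was called higher with 2 of 14 members up, 1 down and 11 not called (6 up and 1 down when adjusted over the list alone; median log2 fold change 0.13, camera adjusted p = 0.0190, adjusted p = 0.289 with an estimated correlation). Its called members were LAMA3 (log2 fold change -0.72), the protease inhibitor gene TIMP2 (0.44) and the integrin gene ITGB1 (0.11). The list call was lost without HOXD13 replicate 1 (adjusted p = 0.0588) or 2 (0.0744), and the ITGB1 call without empty-vector replicate 1 (0.0940) or 2 (0.142). Among markers of other cell types, the collagen genes COL6A1 (log2 fold change 0.24) and COL6A2 (0.31) rose of 3 tested fibroblast genes. VWF (0.52) rose of 4 tested endothelial genes. With limma on log2(FPKM + 1) the calls of COL6A1 (adjusted p = 0.106), COL6A2 (0.122) and VWF (0.130) were lost. The COL6A1 call was lost without empty-vector replicate 1 (adjusted p = 0.0995, log2 fold change 0.15) and the COL6A2 call without empty-vector replicate 2 (0.293, 0.18). Without empty-vector replicate 1 the COL6A2 log2 fold change was 0.47. The 3 tested leukocyte genes had adjusted p from 0.188 for LYZ to 0.694, with CD68 at 0.640.

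Androgen-induced genes rose more often than they fell, and the list was not uniform. Of 30 tested androgen-induced genes, 14 rose, 5 fell and 11 were not called (15 higher and 5 lower when adjusted over the list alone). TMPRSS2, a membrane serine protease gene, rose from 155 ± 0.792 to 264 ± 3.76 FPKM (SD, n = 2; log2 fold change 0.75, SE 0.0317, adjusted p = 5.25e-18). KLK3, which encodes prostate-specific antigen, rose from 2059 ± 21.5 to 3197 ± 81.4 FPKM (log2 fold change 0.61, adjusted p = 5.25e-18). ADAMTS1 (log2 fold change 0.60) and NDRG1 (0.59) also rose. The members that fell were HERC3 (log2 fold change -0.58), FKBP5 (-0.25), ELL2 (-0.21), SORD (-0.19) and NCAPD3 (-0.17), named after their values were seen. FKBP5 encodes a co-chaperone of steroid receptors. The list was called higher (median log2 fold change 0.13, camera adjusted p = 0.0190, adjusted p = 0.441 with an estimated correlation). The list call was lost without empty-vector replicate 1 (adjusted p = 0.135, median 0.07) or HOXD13 replicate 1 (0.0804). The ELL2 call was lost without empty-vector replicate 1 (0.0567), empty-vector replicate 2 (0.0875) or HOXD13 replicate 2 (0.0879), and the NCAPD3 call without empty-vector replicate 1 (0.119). KLK3, HERC3 and FKBP5 had fractional counts.

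Genes of prostate luminal identity were higher in 7 of 15 cases and lower in 1, with 7 not called (8 higher and 1 lower when adjusted over the list alone; median log2 fold change 0.11, camera adjusted p = 0.00623, adjusted p = 0.288 with an estimated correlation). With the trends removed the median was 0.07. ACPP (log2 fold change 0.85), KLK3 (0.61), the cation channel gene TRPM8 (0.57) and the metalloreductase gene STEAP2 (0.47) led the rises, and HOXB13 (-0.11) was the member that fell, a call lost without empty-vector replicate 1 (adjusted p = 0.311) or 2 (0.0701) and with the trends removed (0.0896). Of 5 androgen-repressed genes, 2 rose, 2 fell and 1 was not called, with a median log2 fold change of 0.11 against a mean of -0.05 and a camera adjusted p of 0.594 in the upward direction. With the trends removed the median was 0.05. The pair that fell, the near-identical glucuronosyltransferase genes UGT2B15 and UGT2B17, had a log2 fold change of -0.73 when summed (SE 0.143, adjusted p = 0.000410). Taken singly, UGT2B15 lost its call without empty-vector replicate 1 (adjusted p = 0.0901) or 2 (0.0553) or HOXD13 replicate 1 (0.260, log2 fold change -0.51), and UGT2B17 without empty-vector replicate 2 (0.134). CAMK2N1 rose (log2 fold change 0.54). Of 18 neuroendocrine genes, 4 were tested, too few for a list test. Of these 4, 3 rose: SYT4 (log2 fold change 1.06), ENO2 (0.81) and DDC (0.45). ENO2 also belongs to the hypoxia and glycolysis list and is counted among its rises. Of 15 markers of basal cells and androgen-independent prostate lines, 5 had enough counts to be tested. Their list was called higher with 2 of the 5 up and 3 not called (median log2 fold change 0.44, camera adjusted p = 0.0168, adjusted p = 0.289 with an estimated correlation). KRT14, a basal keratin gene, was at 1.46 ± 0.304 and 3.57 ± 0.297 FPKM (log2 fold change 1.27, adjusted p = 0.00509), and EGFR at 14.2 ± 1.44 and 19.5 ± 0.0283 FPKM (0.44, adjusted p = 9.27e-06). That list call was lost without HOXD13 replicate 1 (adjusted p = 0.0804), and the KRT14 call without empty-vector replicate 2 (0.0669).

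Among cell cycle genes of both phases examined, the called changes were falls. Of 23 G1/S genes, 15 fell and 8 were not called (16 lower when adjusted over the list alone; median log2 fold change -0.20, camera adjusted p = 1.87e-06, adjusted p = 0.256 with an estimated correlation). The helicase subunit gene MCM7 fell from 133 ± 1.02 to 109 ± 5.26 FPKM (SD, n = 2; log2 fold change -0.31, adjusted p = 7.21e-07) and MCM2 from 73.9 ± 3.66 to 62.3 ± 0.375 FPKM (-0.26). Of 25 G2/M genes, 14 fell and 11 were not called (19 lower when adjusted over the list alone; median log2 fold change -0.20, camera adjusted p = 2.34e-07, adjusted p = 0.256 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 84.4 ± 2.74 to 64.4 ± 0.445 FPKM (log2 fold change -0.41, adjusted p = 1.29e-06), and the mitotic kinase gene PLK1 from 65.8 ± 4.91 to 52.4 ± 0.474 FPKM (-0.34). Replication-dependent histone genes were not called as a list (1 of 9 higher and 2 lower, also when adjusted over the list alone; median log2 fold change -0.06, camera adjusted p = 0.530). The histone median changed with the libraries, to 0.01 and -0.14 without empty-vector replicates 1 and 2 and to 0.04 and -0.19 without HOXD13 replicates 1 and 2. HIST1H1C had the largest fall among called members (log2 fold change -0.47).

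The called changes were falls among heat shock genes and rises among genes of endoplasmic reticulum chaperones. Of 14 heat shock genes, 12 fell and 2 were not called (13 lower when adjusted over the list alone; median log2 fold change -0.28, camera adjusted p = 9.52e-08, adjusted p = 0.256 with an estimated correlation). HSPA8, a constitutive cytosolic chaperone gene, fell from 990 ± 4.68 to 794 ± 9.16 FPKM (log2 fold change -0.33, adjusted p = 3.33e-11) and the mitochondrial chaperonin gene HSPD1 from 484 ± 0.474 to 383 ± 9.95 FPKM (-0.35, adjusted p = 1.76e-10). HSPA1A and HSPA1B are near-identical copies, and their sum had a log2 fold change of -0.26 (adjusted p = 3.84e-05). Of 20 genes of endoplasmic reticulum chaperones and the unfolded protein response, 14 rose and 6 were not called (15 higher when adjusted over the list alone; median log2 fold change 0.20, camera adjusted p = 7.00e-05, adjusted p = 0.256 with an estimated correlation). SEL1L, of the degradation machinery of that organelle, rose from 21.5 ± 0.417 to 26.0 ± 0.389 FPKM (log2 fold change 0.26), and the disulfide isomerase gene PDIA6 from 132 ± 3.97 to 157 ± 1.41 FPKM (0.23). Targets of ATF4, the transcription factor of the amino acid response, went the other way, with 8 of 20 lower and 12 not called (10 lower when adjusted over the list alone; median log2 fold change -0.15, camera adjusted p = 0.00247, adjusted p = 0.271 with an estimated correlation). The asparagine synthetase gene ASNS (log2 fold change -0.32) and the serine synthesis gene PSAT1 (-0.27) were among them. With the trends removed the median was -0.10 (adjusted p = 0.0353).

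Among hypoxia and glycolysis genes, the called changes were rises. Of 20 tested members, 11 rose and 9 were not called, the same number when adjusted over the list alone (median log2 fold change 0.30, camera adjusted p = 2.79e-06, adjusted p = 0.256 with an estimated correlation). The enolase gene ENO2 rose from 17.2 ± 0.262 to 30.6 ± 2.05 FPKM (SD, n = 2; log2 fold change 0.81, adjusted p = 4.27e-09). The collagen prolyl hydroxylase gene P4HA1 (log2 fold change 0.74, adjusted p = 5.70e-11) and the mitophagy receptor gene BNIP3 (0.42) rose as well. Ribosomal protein genes were called lower, with 21 of 28 lower and 7 not called (26 lower when adjusted over the list alone; median log2 fold change -0.13, camera adjusted p = 1.86e-06, adjusted p = 0.458 with an estimated correlation). RPL14 fell from 880 ± 3.69 to 760 ± 25.8 FPKM (log2 fold change -0.22, or -0.14 with the trends removed). Complex I subunit genes were called lower with 5 of 24 members down and 19 not called, the same number when adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.00204, adjusted p = 0.458 with an estimated correlation). NDUFS3 fell from 75.2 ± 3.56 to 58.6 ± 3.07 FPKM (log2 fold change -0.37). Once expression, length and GC trends were removed, both of these list calls were lost (camera adjusted p = 0.269 for ribosomal proteins and 0.531 for complex I). The medians were then -0.03 for ribosomal proteins and -0.04 for complex I. The complex I call was also lost without HOXD13 replicate 1, at a median of -0.09. The fry test called neither list (adjusted p = 0.0644 for ribosomal proteins and 0.124 for complex I).

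The other lists fixed in advance were not called by camera. Cholesterol synthesis genes were higher in 8 of 24 cases and lower in 2 (9 and 2 when adjusted over the list alone; adjusted p = 0.633), led by the sterol reductase gene TM7SF2 (log2 fold change 0.49). Fatty acid synthesis genes were higher in 6 and lower in 2 of 13 cases, also when adjusted over the list alone (adjusted p = 0.314), with the desaturase genes FADS2 (0.33) and SCD (0.32) higher and ME1 (-0.37) and FASN (-0.14) lower. Of 24 p53 targets, 3 rose and 3 fell (3 and 4 when adjusted over the list alone; adjusted p = 0.287); GDF15 was the leading rise (log2 fold change 1.06). Of 9 Notch pathway genes, 2 rose and 1 fell (3 and 1 when adjusted over the list alone; adjusted p = 0.224). The ligand gene JAG1 rose from 31.0 ± 0.891 to 50.6 ± 1.37 FPKM (log2 fold change 0.69, adjusted p = 9.82e-14). Of 14 immediate early genes, 1 rose and 2 fell (2 and 2 when adjusted over the list alone), among them MYC (log2 fold change -0.26, adjusted p = 5.78e-05). The list was not called (adjusted p = 0.961), and its median lay between -0.04 and 0.05 when 1 library was left out. Of 10 NF-kB and inflammatory genes, NFKB1 (log2 fold change -0.45) and NFKBIA (-0.32) fell, also when adjusted over the list alone (adjusted p = 0.534 for the list). Of 9 WNT targets, RNF43 rose (log2 fold change 0.49) and MYC fell, also when adjusted over the list alone (adjusted p = 0.740 for the list). Of 22 interferon-stimulated genes, XAF1 rose (0.57; not called when adjusted over the list alone; adjusted p = 0.824 for the list). The RNF43 call was lost without empty-vector replicate 1 (adjusted p = 0.212, log2 fold change 0.31). The XAF1 call was lost without empty-vector replicate 1 (0.0984), empty-vector replicate 2 (0.102) or HOXD13 replicate 2 (0.352, log2 fold change 0.38) and with the trends removed (0.0806). In all, camera called 15 of 28 lists, 8 higher and 7 lower. With estimated correlations it called 0, with 5 lists at an unadjusted p under 0.05. The fry test called 17, and these were not the 15 with others added. It did not call ribosomal proteins (adjusted p = 0.0644) or complex I (0.124). It did call the HOX (0.0342), Notch (0.0294), cholesterol (0.0434) and fatty acid (0.0396) lists, which camera did not. The HOX list includes the overexpressed gene HOXD13 itself. Without HOXD13 replicate 1, camera called 9.

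**Figure D3:**
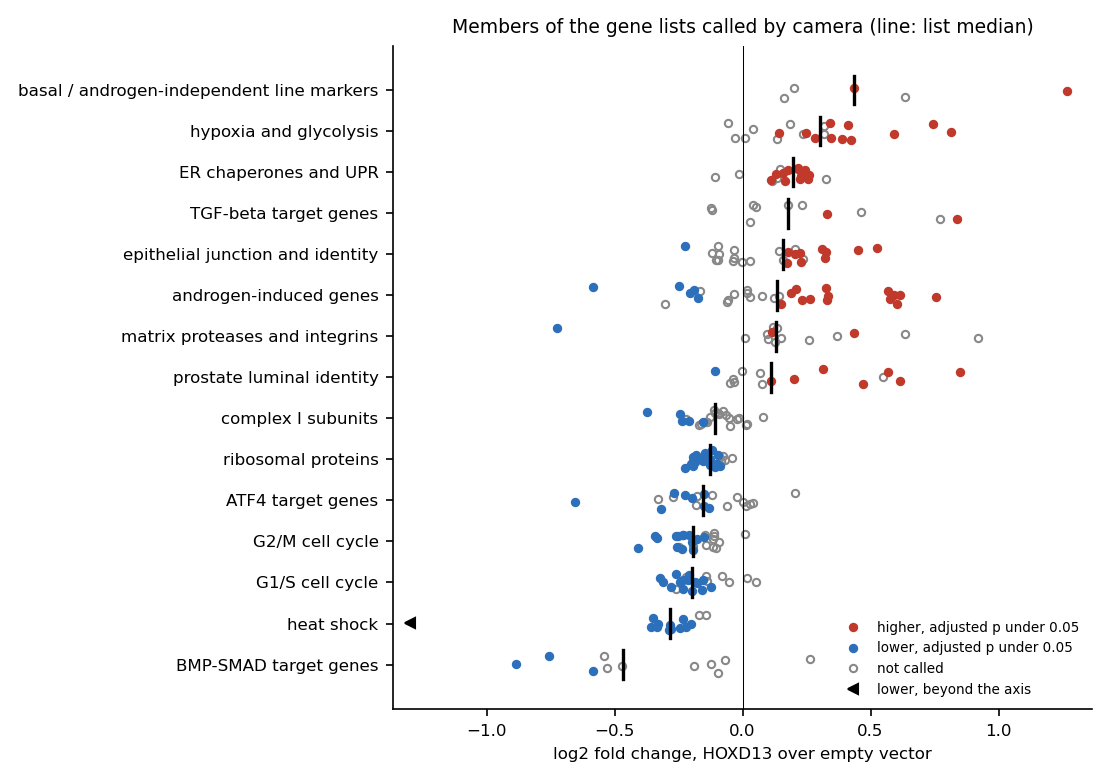
Log2 fold change of HOXD13 over empty-vector libraries (horizontal axis) for each tested member of the 15 gene lists called by camera with its preset correlation, 1 point per gene and a black line at the list median. Filled red and blue points passed an adjusted p of 0.05, open points did not, and the triangle marks HSPA1A, whose reads are shared with HSPA1B, beyond the axis.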

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

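The alternatives were fixed before the data were examined, except the removal of expression, length and GC trends, the sums of near-identical copies and the authors' GO terms, which were chosen after seeing the data. HOXD13 stayed higher in all 10 alternatives that gave a value, with a fitted log2 fold change of 9.30 to 9.57 when 1 library was left out; it was not tested under a mean of at least 50 counts, and DESeq2 gave no adjusted p for HOXD13 or SMAD1. SMAD1 kept its direction, at -0.36 to -0.26 with 1 library left out, and passed the threshold once trends were removed (-0.36). Genes called higher numbered 473 with DESeq2, 398 with limma on log2(FPKM + 1), 382 with a pseudocount of 0.1, 647 at an adjusted p under 0.01, 75 with an added limit of 1 on the absolute log2 fold change, and 751 to 927 with 1 library left out. Genes called lower numbered 577, 261, 265, 633 and 18 in the same order, and 714 to 1064 with 1 library left out (714 without empty-vector replicate 1 and 759 without replicate 2). Fewer genes passed the stricter thresholds by construction; for the tools and left-out libraries the cause was not tested. DESeq2 called 1047 of the 2260 genes, limma 612 and the fit without empty-vector replicate 1 called 1300, all in the same direction. The count of lists called was 0 with estimated correlations, which rest on 2 residual degrees of freedom, and 9 to 14 with 1 library left out. A fit with 1 library in a group assumes that it varies like the other group.

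With the replicate number as a replicate block, 1226 genes were higher and 1297 lower, HOXD13 had a log2 fold change of 9.47 and SMAD1 -0.31, and 14 lists were called; the epithelial list was no longer called (adjusted p = 0.0665). The deviations of libraries that share a number had a correlation across genes of 0.07 over 2 pairs, so the numbers were not taken to pair the libraries. Of 1606 comparisons for 137 genes examined one by one, 1381 kept their side of the threshold, 223 lost it, and 2 turned direction: CD68 without empty-vector replicate 1 (0.13) and VIM without HOXD13 replicate 1 (-0.04, against 0.42 without HOXD13 replicate 2), neither of them called; the cause was not tested. DESeq2 gave an adjusted p for only part of the 137 genes, and 91 of them kept their side of the threshold. For a gene without one, the lack of a listed loss does not mean that DESeq2 called it. Among the 137 genes, limma on log2(FPKM + 1) ended 54 calls and DESeq2 18, and most of these losses are not listed gene by gene above. Those with limma included BMPR2 (adjusted p = 0.0835), LOX (0.0777), TRPM8 (0.072), VWF (0.130), TIMP2 (0.0521), MCM2 (0.0514), SEL1L (0.0551) and FASN (0.0843). Of 251 comparisons for 28 lists, 214 were the same, 33 lost their call and 4 gained one. Depth limited genes near the floor, such as BMP4.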

Other observations

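The tests on GO terms and GAGE copies, and the removal of trends, were chosen only after the results were seen. Among the authors' 971 GO terms of 10 to 300 tested genes, camera called 50 higher and 107 lower; with estimated correlations it called 0 (smallest adjusted p = 0.654), with 49 at an unadjusted p under 0.05, and fry called 34. With expression, length and GC trends removed, 35 terms were higher and 47 lower, among them 32 of the 50 and 47 of the 107. The named examples were chosen after their values were seen. Of 128 tested genes of cell-cell adhesion, 32 rose and 1 fell (camera adjusted p = 1.01e-05, adjusted p = 0.654 with an estimated correlation), among them the desmosomal cadherin gene DSC2 (log2 fold change 0.46) and the adhesion gene MPZL2 (0.52). Of 21 acetylgalactosaminyltransferase genes, 8 rose (camera adjusted p = 0.000381, adjusted p = 0.654 with an estimated correlation), including GALNT3 (log2 fold change 0.50), which starts O-linked glycans, and CHSY1 (0.43), which builds chondroitin sulfate. The oligosaccharyl transferase term had 8 of 10 members higher, including TUSC3 (0.42; camera adjusted p = 0.00412, adjusted p = 0.654 with an estimated correlation). Axon guidance had 9 of 20 higher and 1 lower, including the ephrin gene EFNA5 (0.47; camera adjusted p = 0.00802, adjusted p = 0.654 with an estimated correlation), at a median log2 fold change of 0.31, or 0.18 with the trends removed.

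In 4 terms of protein and RNA production, more genes fell than rose; most genes of each term were not called. Of 46 aminoacyl-tRNA ligase genes, 21 fell (camera adjusted p = 9.90e-06, adjusted p = 0.654 with an estimated correlation), including EPRS (log2 fold change -0.37) and FARSB (-0.33). Of 91 ribosome biogenesis genes, 36 fell and 2 rose (camera adjusted p = 2.25e-06, adjusted p = 0.654 with an estimated correlation), and of 110 genes of the spliceosomal complex 41 fell and 1 rose (camera adjusted p = 2.81e-06, adjusted p = 0.654 with an estimated correlation). Of 82 translation factor genes 36 fell (camera adjusted p = 2.22e-06, adjusted p = 0.654 with an estimated correlation). With the trends removed, camera gave these 4 terms adjusted p from 0.000707 to 0.00455, and their medians lay between -0.13 and -0.10. Other terms of the same theme lost their call: translation (adjusted p = 0.184, median from -0.11 to -0.03), the small ribosomal subunit (0.866) and the large ribosomal subunit (0.516).

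The heat shock, cell cycle and ribosomal protein lists were called lower while fold changes also followed expression and length. The median log2 fold change went from 0.14 in the lowest of 10 bins of expression to -0.06 in the highest, and from -0.06 in the shortest of 10 bins of length to 0.04 in the longest. With these trends and that of GC removed, the medians were -0.22 (SE 0.024) for heat shock, -0.18 (SE 0.041) for G1/S and -0.19 (SE 0.027) for G2/M. Before removal they were -0.28, -0.20 and -0.20. The SE of a list median comes from resampling the genes of the list and holds no spread between libraries. The medians kept most of their size, which argues against the fitted trends as the whole cause in these libraries. The ribosomal protein median shrank from -0.13 to -0.03 (SE 0.013) and its call ended because the fold shrank, so a trend and a change in ribosomal protein genes cannot be told apart with these libraries. For the other 3 lists, slower growth and a difference in culture density stay open and were not tested. Counts of cells of both groups seeded at equal density would show whether growth differs. They would not tie either explanation to the falls of these lists.

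GAGE12F and GAGE2C had counts in both empty-vector libraries and 0 in the HOXD13 libraries, a pattern that could come from reads shared between near-identical copies. The summed family had a log2 fold change of -0.13 (SE 0.0425), the value that loss of the reads held by both copies (8.80% of the family) would give. An exchange of reads between copies alone would leave the sum near the values of other abundant genes, whose median was -0.06 in the highest bin of expression, and the SE does not separate that from -0.13. GAGE6, another copy, had 0 expected counts in replicate 1 of both groups and 89.3 and 88.0 in replicate 2 of the empty-vector and HOXD13 groups, and whether assignment or expression differed there was not tested. An exchange of reads and a loss of both copies therefore cannot be told apart.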
